A study of Mus musculus with 6 samples.

How the data were processed

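RNA of epididymal white adipose tissue (eWAT, the visceral fat pad next to the epididymis) was measured on 6 arrays, 3 from wild-type (WT) mice and 3 from transgenic (Tg) mice that carry Blnc1 in adipose tissue. The mice were male C57BL/6 animals of 8 months that had eaten a high-fat diet for 21 weeks. Total RNA was biotin-labelled for Affymetrix whole-transcript arrays, per the labels. The labels number the replicates of each group 1 to 3 and call them biological, so each array was taken as 1 mouse.

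The deposited values are on the log2 scale, with 1 value per array and row and medians between 2.64 and 2.75. RMA, which corrects background, normalizes between arrays and summarizes probes, and limma were named for this series, per the submitters' processing notes. Their versions and settings, any filter and the genome build were not given in the sources used here. Since RMA normalizes between arrays, a change of total RNA cannot be seen, although the medians are not equal, and differences between low values are compressed toward 0. Detection calls and background levels were not used here, so a gene with a low signal is described by its level and not called absent. The number of arrays, 3 per group, limits the precision.

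The table had 41345 rows. Through the platform's gene annotation, 23521 rows named 1 gene, 1814 named several genes and 16010 named none. Rows with several names or none were tested but not named. The named rows covered 22180 genes. Symbols were set against a RefSeq gene table of assembly GRCm38.p6, which was used only for names, synonyms and the order of neighbouring genes. No coordinates are given because the deposited table names no build.

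Tg was compared with WT row by row with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a 2-sided moderated test on the deposited log2 values, no low-signal filter, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all rows, with a threshold of 0.05. Differences are Tg minus WT on the log2 scale with the standard error (SE) of the fit. An exact permutation test of 3 against 3 arrays cannot give a 2-sided p below 0.1.

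Before the data were examined, 33 gene lists were fixed. They covered white and thermogenic adipocyte genes, metabolic pathways (oxidative phosphorylation, citrate cycle, fatty acid oxidation, lipogenesis, cholesterol synthesis, insulin and glucose handling, branched-chain amino acid catabolism), stress programmes, cell cycle, lysosome, ribosome, immune cells and their programmes, stromal and vascular cells, tissues that a dissection can bring along (epididymis, muscle, blood) and the protein partners of Blnc1. Members were matched by symbol, or else by a synonym that only 1 gene carries, and each gene was represented by its row with the highest mean. The 32 lists with 5 or more measured members were tested with camera of limma at a preset correlation between genes of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list moves on balance 1 way without comparing it with other genes, stood beside it. Counts of single members past the threshold are given over all rows and adjusted over the list alone.

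The rule for the named genes was also fixed before the data were examined. It took 12 genes per direction whose groups did not overlap, those past the threshold first by size and, since there were none, the rest by smallest p. Uncharacterised models and olfactory, vomeronasal and small RNA genes were left out. It further took the 4 members with the smallest p in the list's direction from each list past the threshold, 1 member from each other list, the Blnc1 partners, and Blnc1, Ucp1, Adipoq, Lep, Tnf, Ccl2, Adgre1 and Col1a1. Other genes are named as chosen after their values were seen.

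The procedure was tested on simulated data for the comparison of Tg with WT, over 41345 rows with the real means and fitted spreads. Of 100 rows changed 2-fold, 71% were recovered, and of 100 rows changed 4-fold, 98%. There were 15 false calls among the unchanged rows, and 1 gene list was called, the only shifted one. The simulated genes were independent, so this says nothing about lists whose genes move together. The noise was normal and drawn from the moderated spreads of the fit. The shares recovered thus hold for such simulated rows and may be too high for the real arrays. Alternatives fixed at the start left out each array in turn, added the replicate number as a block, renormalized the arrays in 3 ways (cyclic loess, median centring, quantile), filtered dim rows, kept only rows with 1 gene, changed the variance model, weighted arrays, averaged the rows of a gene and changed thresholds and set tests. A comparison of the 3 arrays without reproductive tract signal and a split of the neutrophil and mast cell list were added after seeing the data.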

Results

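Blnc1 is a long noncoding RNA known from brown fat, where it works with the transcription factor EBF2 to turn on thermogenic genes. The arrays compared the eWAT transcriptome of mice with adipose-specific Blnc1 (3 arrays, Tg 1 to Tg 3) with that of WT mice (3 arrays, WT 1 to WT 3) after 21 weeks of high-fat feeding. Over all rows, Pearson's r between 2 arrays lay between 0.979 and 0.990, a correlation across genes that are not independent replicates.

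No row of the platform carried the symbol Blnc1. The gene table lists Blnc1 as a synonym of Paqr9, a coding gene with 1 row. It read 7.21 ± 0.29 in Tg and 6.44 ± 0.38 in WT (SD, n = 3), with no overlap between the groups. The difference was 0.77 ± 0.23 (SE) and was not past the threshold, with an adjusted p of 0.38 in limma. Whether this row detects the noncoding RNA or the transgene is unknown, so it does not check the genotype labels. The partner genes Ebf2, Zbtb7b and Hnrnpu differed by -0.02, -0.05 and -0.09, each by less than its SE, and all 3 differences changed sign under at least 1 alternative, those of Ebf2 and Zbtb7b with median centring of the arrays. A second, dimmer row of Hnrnpu was lower by -0.38 ± 0.11 with groups apart, and a dim second row of Ebf2 read 0.16 ± 0.14.

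Single genes that stood apart between the genotypes included Pomgnt2, a glycosyltransferase of the dystroglycan pathway, at 7.58 in Tg and 4.24 in WT (10.1-fold; log2 difference 3.34 ± 0.43 SE, n = 3 per group). Phgdh, the first enzyme of serine synthesis, was higher in Tg by 1.01 ± 0.12, the growth factor gene Fgf1 by 0.67 ± 0.09, the imprinted transcription factor gene Plagl1 by 1.05 ± 0.14 in 1 row (0.25 ± 0.19 in its brighter row, groups overlapping), the acute-phase gene Orm2 by 1.44 ± 0.23 and the glucose transporter gene Slc2a12 by 0.83 ± 0.12. Flacc1 (0.90), Gas2l2 (1.42), Prss27 (1.04), Unc93a2 (0.92), Fndc8 (0.71) and Bhlha9 (0.62) were also higher, the last pair at signals below the median of all rows in both groups. Lower in Tg were the mast cell chymase gene Cma1 (-1.58 ± 0.23), the lectin receptor gene Clec4d (-1.36 ± 0.19), Cyp2f2 (-1.48 ± 0.19), a cytochrome P450, and the Wnt antagonist gene Frzb (-0.72 ± 0.12). Uchl1 (-0.75), Olfml3 (-0.63), Chl1 (-0.92), Cers2 (-0.58 in 1 row and -0.18 in its brighter row) and the dim genes Retnlg (-1.12), Xlr4b (-0.80), Rgs13 (-0.67) and Tnfsf4 (-0.66) were lower as well. Dim second rows of Cyp2f2 (0.22 ± 0.13) and Uchl1 (0.13 ± 0.11) pointed the other way.

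**Figure D1:**
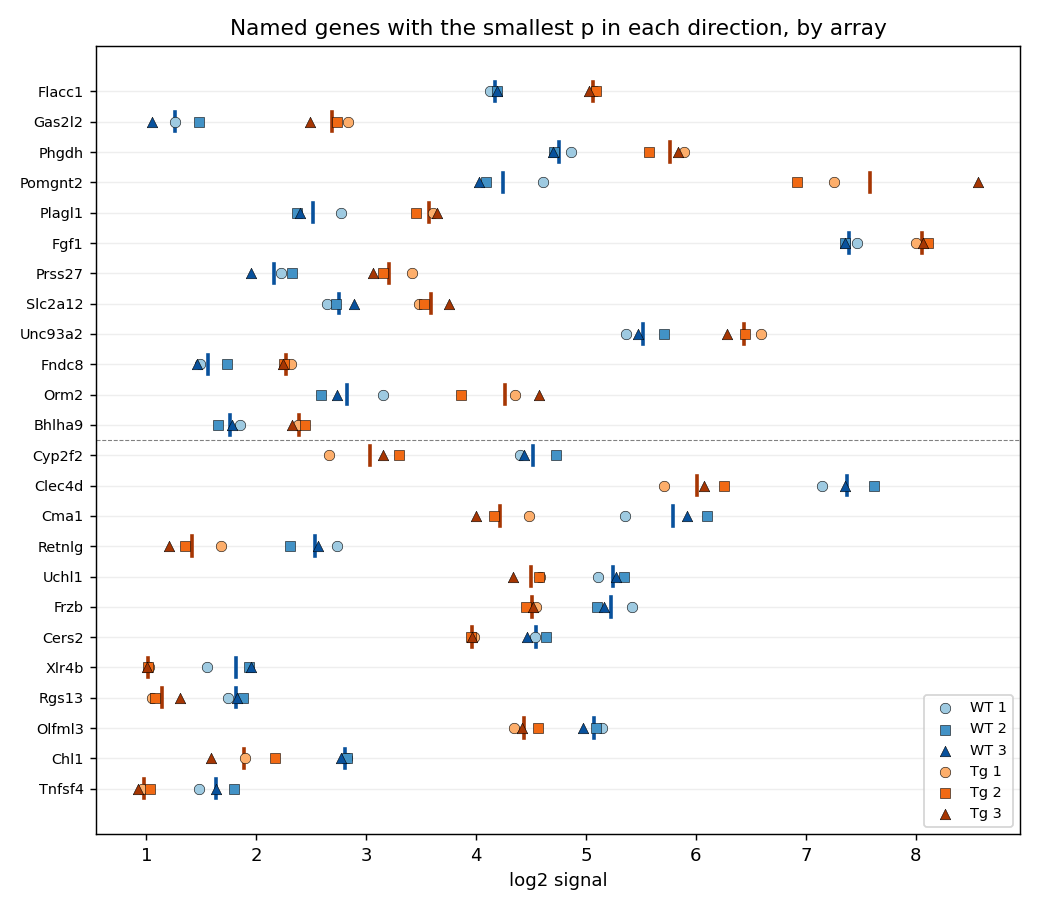
Log2 signal of the 24 named genes with the smallest p, 12 higher in Tg above the dashed line and 12 lower in Tg below it. Each point is 1 array, and the vertical bars are the means of the 3 WT (blue) and 3 Tg (orange) arrays. The groups do not overlap in any of these genes, a condition of their choice, and Pomgnt2 has the widest gap, from 4.61 in the highest WT array to 6.92 in the lowest Tg array.

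None of these genes passed the threshold. Limma gave 0 of 41345 rows at an adjusted p of 0.05 or below, and the smallest adjusted p was 0.196, that of Flacc1. At an unadjusted p under 0.05 there were 4263 rows, 1831 higher and 2432 lower in Tg, where chance gives 2067. The share higher in Tg was 43.0% as deposited and 64.7% with each array centred on its median. The groups did not overlap in 6907 rows, or 16.7%, where chance gives 10%. With only WT 1, Tg 1 and Tg 3, the arrays without reproductive tract signal described below, 2246 rows had an unadjusted p under 0.05. That comparison has WT 1 as its only WT array, which limma's fit assumes to vary like the Tg arrays, so its values describe 1 WT mouse and do not test the genotype.

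Among the genes named at the start, Ucp1, the uncoupling protein of brown and beige fat, was lower in Tg by -1.55 ± 0.30 (2.44 against 3.99 in WT, groups apart). Adipoq, the gene of the hormone adiponectin, was higher by 0.62 ± 0.19 and the leptin gene Lep by 0.36 ± 0.13, both with groups apart, and the macrophage gene Adgre1 was lower by -0.45 ± 0.11. Tnf (-0.23 ± 0.14), Ccl2 (0.32 ± 0.19) and the collagen gene Col1a1 (0.19 ± 0.21) overlapped between the groups. None of the 7 passed, with adjusted p between 0.33 and 0.79, and against WT 1 alone, in the 3 arrays without tract signal, Ccl2 read -0.13 and Col1a1 -0.30.

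At the level of gene lists, 20 of the 32 tested lists passed with camera's preset correlation, 9 higher and 11 lower in Tg. With an estimated correlation 0 passed, 1 at an unadjusted p under 0.05 (median estimated correlation 0.255, and -0.011 in the neutrophil and mast cell list). Fry called 1 list, the neutrophil and mast cell list, and had 7 at an unadjusted p under 0.05, and its test for change in either direction called 10. The adjusted p of each list with an estimated correlation is therefore given beside it. The preset p treats genes as nearly independent and can be far too small where they move together. Every other split of the 6 arrays also gave lists past the threshold at the preset correlation, from 6 to 20. An exact permutation test of the list means gave p = 0.4 for T and NK cell, interferon and MHC class II, 0.8 for epididymis and 0.1 or 0.2 for the other called lists. In the 3 arrays without tract signal, of which 1 is WT, the mean of 4 of the 20 lists had the other sign. Centring each array on its median raised every list mean alike, so small shifts depended on the scaling: lysosome became -0.08 (from -0.15), lipid-associated macrophage -0.08 (from -0.14), endoplasmic reticulum stress -0.01 (from -0.08), citrate cycle 0.21 (from 0.14) and insulin and glucose handling 0.23 (from 0.16).

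Adipocyte genes were higher in Tg. Of 27 measured white adipocyte genes, 26 were higher, by 0.40 on average (1.32-fold, camera adjusted p = 2.8e-10, adjusted p = 0.51 with an estimated correlation), and in 16 all 3 Tg arrays lay above all 3 WT arrays. Examples were Rbp4, the retinol carrier (0.95 ± 0.23), Klb, the FGF21 coreceptor (0.89 ± 0.18), Thrsp, a regulator of lipogenesis (0.80 ± 0.15), and Adipor2, an adiponectin receptor (0.70 ± 0.16). Adjusted over the list alone 10 members passed, and over all rows 0. The array means of the list, relative to the mean of all 6, were -0.07, -0.15 and -0.38 in WT 1 to WT 3 and 0.38, -0.01 and 0.23 in Tg 1 to Tg 3. The arrays with reproductive tract transcripts (WT 2, WT 3 and Tg 2) were the lowest of their groups.

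Genes of fatty acid synthesis and use were higher as well, but the lists are not independent. Thrsp, Lpin1, Dgat2 and Slc2a4 are in both the white adipocyte and the lipogenesis list, and Fabp4 and Cd36 in the white adipocyte and the endothelial list. The lipogenesis, fatty acid oxidation, branched-chain amino acid, citrate cycle, insulin and endothelial lists also ranked the arrays within each group as the white adipocyte list did. In de novo lipogenesis 21 of 25 members were higher, by 0.34 on average (adjusted p = 2.6e-09, adjusted p = 0.51 with an estimated correlation), with Mlxipl, the gene of the transcription factor ChREBP (0.61 ± 0.12), the acetyl-CoA synthetase gene Acss2 (0.51 ± 0.13) and Pnpla3 (0.44 ± 0.11), and 9 passed when adjusted over the list alone. All 24 measured genes of fatty acid oxidation were higher, by 0.25 on average (adjusted p = 1.6e-07, and 0.51 with an estimated correlation), among them Ehhadh (0.59 ± 0.17), Decr1 (0.38 ± 0.12), Hadh (0.36 ± 0.13) and Acaa1b (0.61 ± 0.22). Branched-chain amino acid catabolism was higher in 19 of 21 genes, by 0.26 (camera adjusted p = 1.2e-06, and 0.51 with an estimated correlation). Examples were Bckdhb (0.55 ± 0.13) and Dbt (0.45 ± 0.13), genes of the branched-chain dehydrogenase complex, Hibch (0.48 ± 0.14) and Aldh6a1 (0.43 ± 0.17). In these last 2 lists, adjusted over the list alone, 0 members passed in limma, with 8 and 6 at an unadjusted p under 0.05. Tg 2 lay below WT 1 in fatty acid oxidation, with array means of -0.03 and -0.01.

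Smaller shifts in the same direction were found in 3 further metabolic lists. Cholesterol synthesis was higher in 16 of 19 genes by 0.22 (adjusted p = 1.1e-04), with Hmgcs1 (0.57 ± 0.14), Insig1 (0.43 ± 0.13), Fdft1 (0.40 ± 0.13) and Sc5d (0.41 ± 0.15), and averaged 0.04 in the 3 arrays without tract signal. The citrate cycle was higher in 20 of 22 genes by 0.14 (adjusted p = 4.7e-04), led by the pyruvate carboxylase gene Pcx (0.55 ± 0.15) and Idh3a (0.38 ± 0.13), with Cs at 0.16 ± 0.09 and Mdh2 at 0.18 ± 0.11; without Tg 1 the shift was 0.09. Insulin and glucose handling was higher in 18 of 23 genes by 0.16 (adjusted p = 0.0081), with Foxo1 (0.38 ± 0.12), Irs2 (0.55 ± 0.18) and Pck1 (0.52 ± 0.22), and its call was lost without WT 3 (shift 0.10, adjusted p = 0.096) and without Tg 1 (0.12, adjusted p = 0.067). For all 3 lists the adjusted p was 0.51 with an estimated correlation, and the array means of the groups overlapped. Tg 2 lay below WT 1 in the citrate cycle (-0.04 and -0.01) and in insulin and glucose handling (-0.02 and 0.03). In cholesterol synthesis Tg 1 lay below WT 1 (-0.06 and 0.04). Adjusted over the list alone, 2 insulin and glucose genes passed, Mlxipl upward and Slc2a1, the basal glucose transporter, downward (-0.47 ± 0.10, but 0.16 ± 0.19 in a dim second row), and 0 of the other 2 lists, which had 5 and 2 members at an unadjusted p under 0.05.

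Endothelial genes were higher in all 26 measured members, by 0.35 on average (1.28-fold, adjusted p = 7.6e-08, adjusted p = 0.51 with an estimated correlation), with Lyve1, a lymphatic marker (0.66 ± 0.14), the phosphatase gene Ptprb (0.58 ± 0.17), Erg (0.55 ± 0.19) and Vegfa, the growth factor itself (0.43 ± 0.14). The groups did not overlap in 6 members, and 0 passed when adjusted over the list alone in limma, with 7 at an unadjusted p under 0.05. WT 3 was the lowest array at -0.46, and without it the shift was 0.21. Tg 2 lay below WT 1, with array means of 0.02 and 0.06.

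**Figure D2:**
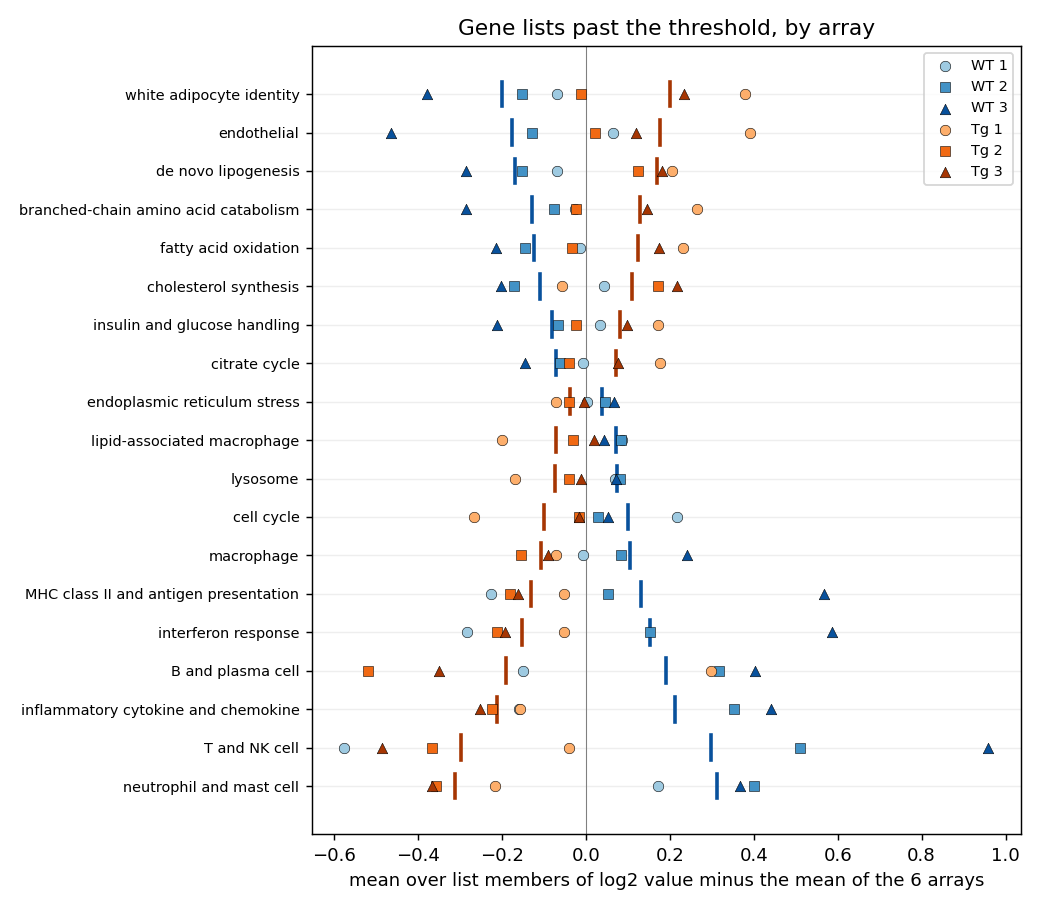
Mean over the measured members of each gene list of the log2 value minus the mean of the 6 arrays, for the 19 lists past the threshold other than the epididymis list. Each point is 1 array, and vertical bars are the means of the 3 WT (blue) and 3 Tg (orange) arrays. WT 1 lies with the Tg arrays in the T and NK cell, interferon and inflammatory lists, at -0.58, -0.28 and -0.16.

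Mast cell genes were lower in Tg. The neutrophil and mast cell list was lower in 18 of 23 members, by -0.63 on average (adjusted p = 1.6e-07, adjusted p = 0.11 with an estimated correlation, 0.0099 in fry), and 9 members passed when adjusted over the list alone. The mast cell protease genes Cma1 (-1.58 ± 0.23), Mcpt4 (-1.58 ± 0.31) and Tpsb2 (-1.51 ± 0.30) and the neutrophil gene Retnlg (-1.12 ± 0.17) had the smallest p. After seeing this the list was split. All 9 mast cell members were lower, by -1.27 on average (2.41-fold, adjusted p = 1.9e-10, adjusted p = 0.51 with an estimated correlation, 0.23 in fry), 8 of them with groups apart. The 14 neutrophil members averaged -0.21 and were not past the threshold (adjusted p = 0.057). The array means of the mast cell members were 0.02, 1.09 and 0.80 in WT 1 to WT 3 and -0.41, -0.65 and -0.83 in Tg 1 to Tg 3, so WT 2 and WT 3, which carried reproductive tract transcripts, were the highest. In the 3 arrays without such transcripts the shift was -0.64, against 1 WT array.

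Macrophage genes were lower by a small amount. In 23 of 28 members Tg was lower, by -0.21 on average (adjusted p = 1.3e-06, adjusted p = 0.51 with an estimated correlation), and in 17 the groups were apart, among them Adgre1, the complement gene C1qc (-0.47 ± 0.14), the scavenger receptor gene Msr1 (-0.46 ± 0.14) and Tyrobp (-0.29 ± 0.11). In the 3 arrays without tract signal the shift was -0.08, against 1 WT array. Lipid-associated macrophage genes were lower in 20 of 24 members by -0.14 (adjusted p = 0.0020), with the proton channel gene Hvcn1 (-0.48 ± 0.11), the protease gene Ctsk (-0.61 ± 0.16), Trem2 (-0.25 ± 0.10) and Nceh1 (-0.31 ± 0.14, but 0.05 over the mean of its rows), and lost the call without Tg 1 (-0.08, adjusted p = 0.072). Lysosomal genes were lower in 25 of 28 members by -0.15 (adjusted p = 4.7e-05), with Ctsz (-0.30 ± 0.10), Gusb (-0.31 ± 0.11) and Ctsh (-0.24 ± 0.10) beside Ctsk. Both of these lists had an adjusted p = 0.51 with an estimated correlation. They share Ctsb, Ctsd, Ctsk, Ctsl, Lipa and Cd63, and Cd68 is in the macrophage and the lysosome list, so the shifts are not independent. The lipid-associated macrophage list also holds Lpl, Fabp4 and Cd36 of the white adipocyte list. Adjusted over each of the 3 lists alone, 0 members passed in limma, with 13, 4 and 5 at an unadjusted p under 0.05.

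Inflammatory cytokine and chemokine genes were lower in 27 of 32 members, by -0.42 on average (adjusted p = 1.6e-05, adjusted p = 0.51 with an estimated correlation). Examples were the chemokine genes Ccl3 (-0.70 ± 0.14) and Ccl4 (-0.67 ± 0.17) and the interleukin genes Il1b (-0.63 ± 0.16) and Il1a (-0.30 ± 0.09, a dim gene). The list also holds Ptgs2, which read 7.80 and 9.04 in WT 2 and WT 3 and between 3.27 and 3.96 in the other 4 arrays. WT 1 read -0.16, level with the Tg arrays, and in the 3 arrays without tract signal the shift was -0.05. Adjusted over the list alone, 0 members passed in limma, with 9 at an unadjusted p under 0.05.

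Lymphocyte and interferon genes were also lower on average. T and NK cell genes were lower in 26 of 29 members by -0.60 (adjusted p = 8.9e-05), with the granzyme gene Gzmb (-1.39 ± 0.48), Gata3 (-1.18 ± 0.55), Cd3g (-1.16 ± 0.62) and Cd8b1 (-1.01 ± 0.53). Interferon-response genes were lower in 27 of 30 members by -0.30 (adjusted p = 1.6e-04), with Mx1 (-0.66 ± 0.21, dim), Rsad2 (-0.27 ± 0.10), Irgm2 (-0.75 ± 0.37) and Mx2 (-0.30 ± 0.17). All 18 MHC class II and antigen presentation genes were lower, by -0.26 (adjusted p = 0.0022), with Ctss (-0.29 ± 0.12), Itgax (-0.30 ± 0.14), Ccr7 (-0.42 ± 0.24) and H2-Aa (-0.29 ± 0.20). B and plasma cell genes were lower in 18 of 19 members by -0.38 (adjusted p = 0.0019), with Cd22 (-0.42 ± 0.12), Ighm (-0.63 ± 0.28), Fcrla (-0.51 ± 0.21) and the dim Tnfrsf17 (-0.52 ± 0.25). For all 4 lists the adjusted p was 0.51 with an estimated correlation. Members are shared with other lists here too. Cxcl9 and Cxcl10 are in the interferon and the inflammatory list. Of the MHC class II list, Ctss is also in the lysosome list and Itgax in the lipid-associated macrophage list.

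The T and NK cell means were -0.58, 0.51 and 0.96 in WT 1 to WT 3 and -0.04, -0.37 and -0.49 in Tg 1 to Tg 3, so WT 1 was the lowest of all arrays. Without WT 3 the T and NK cell shift was -0.27 (adjusted p = 0.067), the interferon shift -0.09 (0.15) and the MHC class II shift -0.04 (0.47), and without WT 1 they were -1.03, -0.52 and -0.44. The B and plasma cell shift was -0.22 without Tg 2 (0.060) and -0.62 without Tg 1. In that list Tg 1 lay above WT 1, with array means of 0.30 and -0.15. In the 3 arrays without tract signal all 4 lists were higher in Tg, which rests on WT 1 alone. Adjusted over the lists alone, 0 members passed in limma, with 1, 2, 1 and 2 at an unadjusted p under 0.05.

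Cell cycle genes were lower in 27 of 29 members, by -0.20 on average (adjusted p = 3.4e-06, adjusted p = 0.51 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 (-0.47 ± 0.10, but 0.38 ± 0.21 in a dim second row), Aurkb (-0.40 ± 0.11), Mcm5 (-0.37 ± 0.10) and Pcna (-0.33 ± 0.10). Without Tg 1, the lowest array, the shift was -0.12. Endoplasmic reticulum stress genes were lower in 18 of 24 members by -0.08 (adjusted p = 0.040, adjusted p = 0.51 with an estimated correlation), with Ern1 (-0.33 ± 0.10), Hspa5 (-0.25 ± 0.12), Manf (-0.27 ± 0.13) and Sdf2l1 (-0.26 ± 0.15), and this call was lost without WT 2 (0.090), WT 3 (0.11), Tg 1 (0.14) or Tg 2 (0.054). Adjusted over the lists alone, 0 members of either passed in limma, with 5 and 1 at an unadjusted p under 0.05.

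Transcripts of the epididymis, the organ the fat pad is attached to, were present in 3 of the 6 arrays. In Tg 2, 14 of 31 measured epididymis genes lay at least 4 log2 units above their lowest array, among them the glutathione peroxidase gene Gpx5 at 10.77 and the lipocalin genes Lcn9 at 9.87 and Lcn8 at 8.81. In WT 2 and WT 3 other members were high, 2 and 3 in number, including Spink8 at 6.55 and 8.09 and Serpina1f at 6.58 and 8.09. WT 1, Tg 1 and Tg 3 had 0 such genes, although Gpx5 read 3.22 in Tg 1. The list passed as higher in Tg (0.77, adjusted p = 0.022, adjusted p = 0.63 with an estimated correlation), but without Tg 2 it was lower (-0.28, adjusted p = 0.75) and without WT 1 the call was lost (0.39). Without Tg 1 and without Tg 3 the shift was 1.25 and 1.35. Gpx5 (3.92 ± 2.33), Lcn9 (3.17 ± 2.24), Lcn12 (0.49 ± 0.33) and Spint4 (0.15 ± 0.09) did not pass when adjusted over the list alone, nor did any other member in limma, with 1 at an unadjusted p under 0.05.

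**Figure D3:**
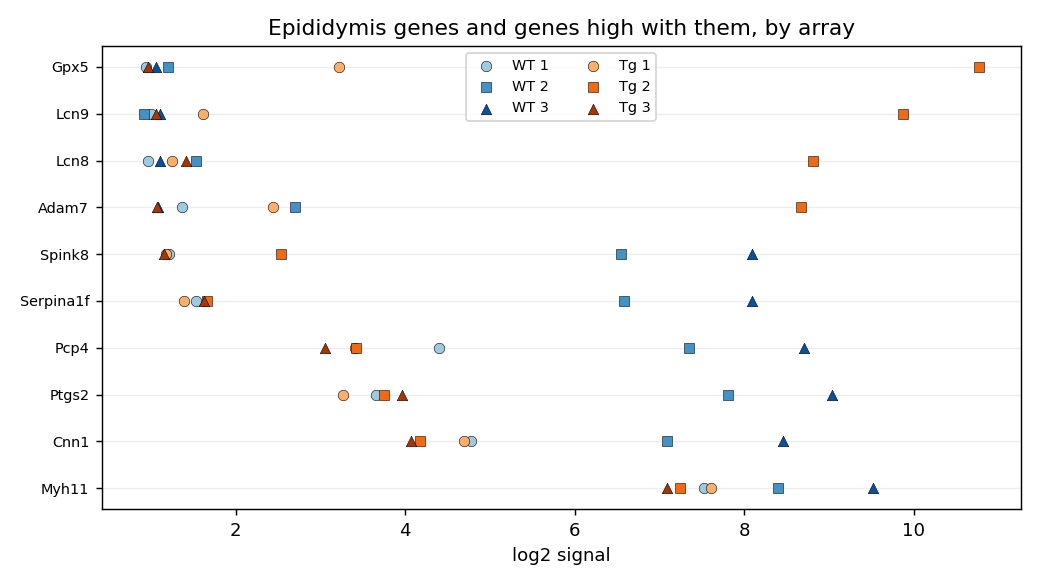
Log2 signal of 4 epididymis genes that were high in Tg 2, 2 that were high in WT 2 and WT 3, and 4 further genes high in WT 2 and WT 3, chosen after their values were seen. Each point is 1 array of 1 mouse, in blue for WT and orange for Tg. Gpx5 reads 10.77 in Tg 2 and 3.22 or less elsewhere, and Spink8 reads 6.55 and 8.09 in WT 2 and WT 3 and 2.53 or less elsewhere.

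The other 12 tested lists did not pass. Thermogenic and brown fat genes averaged 0.03 (17 of 27 higher, adjusted p = 0.45), although Ucp1 and Tmem26, a beige fat marker (-0.62 ± 0.14), passed as lower when adjusted over the list alone. Oxidative phosphorylation genes averaged 0.04 (36 of 51 higher, adjusted p = 0.10, with Ndufb9 at 0.34 ± 0.12) and extracellular matrix genes 0.09 (32 of 50 higher, adjusted p = 0.10, with Mmp3 at -0.97 ± 0.20). Both depended on single arrays. Camera's adjusted p for oxidative phosphorylation was 0.033 without Tg 3 and 0.80 without Tg 1. For matrix it was 2.1e-05 without WT 1 and 0.94 without WT 3. In the 3 arrays without tract signal the matrix list averaged -0.14, with WT 1 the highest of all arrays at 0.18. Adipose progenitor genes averaged 0.10 (adjusted p = 0.25), with Wnt2 (0.54 ± 0.09, dim) and Sema3c (0.68 ± 0.15) past the threshold over the list alone. Oxidative stress genes averaged -0.07 (adjusted p = 0.45), and 3 passed as lower over the list alone, the cystine transporter gene Slc7a11 (-0.99 ± 0.18, but -0.05 ± 0.12 in a dim second row), Srxn1 (-0.66 ± 0.12) and Hmox1 (-0.60 ± 0.14). Hypoxia genes averaged 0.11 (adjusted p = 0.23), with Slc2a1 lowest in p.

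Pericyte and smooth muscle genes averaged -0.24 (adjusted p = 0.69, with Synpo2 at 0.71 ± 0.20 but, picked after their values were seen, Cnn1 at -2.46 ± 0.86 and Myh11 at -1.17 ± 0.48, both highest in WT 2 and WT 3), skeletal muscle genes 0.08 (0.25, with Myl1 at 0.57 ± 0.17), erythroid and blood genes 0.15 (0.45, 5 measured, with Itga2b at -0.42 ± 0.18), immediate early genes -0.07 (0.17, with Zfp36 at -0.37 ± 0.10) and cytosolic ribosome genes -0.02 (0.45, with Rps18 at 0.51 ± 0.28). Dimmer rows of Rps18 read -0.05 ± 0.14 and 0.03 ± 0.09, and its brightest row was highest in Tg 2, at 6.08. The mesothelial list averaged -0.03 while its test pointed upward (adjusted p = 0.77), with Igfbp5 at 0.34 ± 0.13. Adjusted over the list alone 0 members of the oxidative phosphorylation, matrix, hypoxia and these 6 lists passed in limma, with 3, 9, 5, 6, 2, 0, 2, 0 and 1 at an unadjusted p under 0.05.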

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

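The 3-array comparison, the split of the neutrophil and mast cell list and the count at an unadjusted p were chosen after seeing the data. The 3 arrays hold 1 WT array, assumed to vary like the Tg arrays, so the values from them describe that mouse and decide nothing about the genotypes. The count of 0 rows past the threshold held under every alternative at an adjusted p, that at 0.10 included, against 1552 rows at an unadjusted p under 0.05 with a 1.5-fold difference. The 4263 rows at an unadjusted p became 2721 among rows that name 1 gene, since fewer rows were tested, 2246 in the 3 arrays, and 3104 to 5089 with 1 array left out. The difference of the Paqr9 row kept its sign and stayed outside the threshold throughout, from 0.53 in the 3 arrays to 0.97, and between 0.59 and 0.97 with 1 array left out. The groups did not overlap in this row, so leaving out arrays could change the size of its difference but not the sign. In place of 20 lists, 15 to 21 passed with 1 array left out, 0 with an estimated correlation and 1 in fry. In the 3 arrays 4 of the 20 called lists turned to the other direction. Over 119 named genes 1872 results kept sign and side and 17 turned. No row passed at an adjusted p in any of these fits, so the side was the same throughout. Many of these genes had groups that did not overlap, a condition of choice for those with the smallest p. Leaving out arrays could not turn their sign, so the 1872 are largely fixed by the choice of genes. Over 32 lists 492 results kept sign and side, 66 were lost, 6 gained and 13 turned. The replicate block gave 0 rows past the threshold, 4034 rows at an unadjusted p and 20 lists, so it changed no call. Same-numbered WT and Tg arrays did not deviate together (r = -0.04, 0.01 and -0.04). With 3 arrays per group and tract signal in some of them, this cannot show whether the numbers mark pairs of mice, which stays unknown. Signal over background is unknown, which limits the genes with low signals.

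With an estimated correlation the adjusted p was 0.11 for neutrophil and mast cell, 0.63 for epididymis and 0.51 for the other 18 called lists. In fry it was 0.22 for white adipocyte, macrophage, inflammatory, endoplasmic reticulum stress and lysosome, 0.23 for fatty acid oxidation, 0.16 for lipogenesis, 0.29 for branched-chain amino acids, lipid-associated macrophage and cell cycle, 0.30 for citrate cycle, endothelial and cholesterol synthesis, 0.36 for insulin, 0.47 for interferon, MHC class II and B cells, 0.48 for T and NK cells and 0.54 for epididymis. In the 3 arrays the adjusted p was 0.69 for cholesterol synthesis, 0.17 for insulin, 0.13 for macrophage, 0.35 for inflammatory and 0.38 for epididymis and endoplasmic reticulum stress, all outside the threshold, and the direction of the test turned for interferon (0.0044), MHC class II (0.13), T and NK cells (2.1e-04), B cells (0.38), matrix (0.0035) and thermogenic genes (0.69). The single genes that turned there were Ccl2 (-0.13), Col1a1 (-0.30), Hnrnpu (0.016), Irgm2 (0.047), H2-Aa (0.13), Cd8b1 (0.17) and Cd3g (0.35). The neutrophil members alone gave 0.057.

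The epididymis call was lost with cyclic loess (0.062), median centring (0.12), quantile normalization (0.089), the dim-row filter (0.84) and array weights (0.11), and that of endoplasmic reticulum stress with median centring (0.090), the filter (0.090) and the mean of rows (0.058). The mesothelial test turned with median centring (0.82), and its mean, near 0, changed sign under further alternatives, 0.013 in the 3 arrays among them. Ebf2 turned with median centring (0.044), array weights (0.0013) and the mean of rows (0.068), Zbtb7b with cyclic loess (0.0020), median centring (0.019) and quantile normalization (0.032), and Nceh1 with the mean of rows (0.053). With 1 array left out the adjusted p ranged from 8.7e-05 to 0.75 for epididymis, 0.028 to 0.14 for endoplasmic reticulum stress, 0.0011 to 0.096 for insulin, 3.0e-10 to 0.15 for interferon, 5.2e-06 to 0.47 for MHC class II, 6.3e-16 to 0.067 for T and NK cells, 3.4e-04 to 0.072 for lipid-associated macrophage, 6.3e-08 to 0.060 for B cells, 0.15 to 0.93 for mesothelial, 0.20 to 0.82 for pericyte and 0.097 to 0.86 for ribosome. Ebf2 ranged from -0.080 to 0.050 and Zbtb7b from -0.14 to 0.11. Where no reason is given, the cause was not tested.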

Other observations

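The genes in this paragraph and the next were chosen after their values were seen, and none passed over all rows. Further mast cell genes lay in the direction of the mast cell members: the receptor gene Mrgprb1 was lower in Tg by -2.12 ± 0.44, Mrgprb2 by -1.17 ± 0.35, the serotonin synthesis gene Tph1 by -1.85 ± 0.53 and the serotonin transporter gene Slc6a4 by -1.17 ± 0.22 (SE, n = 3 per group). Part of these differences lay in WT 2 and WT 3, the WT arrays with tract signal: Mrgprb1 read 4.57 in WT 1 against 6.34 and 5.92, Tph1 3.12 against 5.30 and 4.66, and Mrgprb2 2.33 against 3.75 and 3.02. Cd5l, a macrophage-secreted protein gene, was lower by -1.90 ± 0.39, with array values of 5.07, 5.30 and 4.78 in WT and 4.07, 2.71 and 2.68 in Tg. The macrophage gene Ms4a6d was lower by -0.64 ± 0.11.

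Phgdh, the first step of serine synthesis, stood apart between the groups, while the next enzymes Psat1 (0.33 ± 0.16, groups also apart) and Psph (0.07 ± 0.12, groups overlapping) differed less. Of the oxidative stress list, Gstm2 (0.36), Sod2 (0.34) and Sod3 (0.55) were higher. Pcolce2, the measured neighbour gene of Paqr9, was higher by 0.57 ± 0.13.

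The tests of the 3 patterns below and the splits at an unadjusted p were chosen after the results were seen, and the counts over other splits for rows past the threshold and for gene lists were planned. The 6 arrays form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 rows past the threshold and the highest other split also 0, so all 10 splits gave as many. It gave 4263 rows at an unadjusted p under 0.05, against 2437 in the highest other, so 1 of 10 splits reached it, and it gave 20 gene lists, against 20 in the highest other, so 2 of 10 splits reached it. The split with 2437 rows set WT 1, Tg 1 and Tg 3 against the 3 arrays with reproductive tract transcripts and gave 19 lists. The split with 20 lists set WT 1, Tg 1 and Tg 2 against WT 2, WT 3 and Tg 3.

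Epididymis genes were high in Tg 2. In that array 13 members of the list lay at least 4 log2 units above both other Tg arrays, and epididymal tissue taken with the fat is a candidate source. None of the fixed members is in another list. In the arrays without this signal, 1 of the 31 measured lay over the median of all rows. Those arrays were picked for a lack of high members, so this is no separate support. In Tg 1 and Tg 3, 0 members lay at least 4 log2 units above their lowest array, which argues against an effect of the transgene on these genes. Smaller rises were not counted, such as Gpx5 at 3.22 and Adam7 at 2.44 in Tg 1. A wrong group label on Tg 2 stays open: of 24 genes chosen on the other 5 arrays, 17 placed Tg 2 nearer to the other Tg arrays, below the 18 set as the bound.

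Some gene lists that differed between the genotypes also differed between WT 1 and the WT arrays with tract signal. For T and NK cell genes the mean of Tg 1 and Tg 3 lay 0.31 above WT 1, and the lower level in Tg rests on WT 2 and WT 3, where tissue of the reproductive tract and its lymphocytes may be a source. This stays open, since WT 1 is 1 mouse. Tg 2, with 14 high tract genes, lay between Tg 1 and Tg 3 (-0.37, against -0.04 and -0.49). However, Spink8 and Serpina1f, high in WT 2 and WT 3, read 2.53 and 1.66 in Tg 2. The tract signal of Tg 2 thus differed in kind, and its level cannot show what such tissue brought into WT 2 and WT 3. A genotype effect shared by all animals stays untested there, since WT 1, at -0.28 relative to the Tg mean, is 1 mouse. White adipocyte genes were 0.38 higher in Tg 1 and Tg 3 than in WT 1, near the 0.40 of all arrays, but with 1 WT array the share of tract tissue and of genotype cannot be told apart. For mast cell genes, dilution of fat RNA by tract tissue would lower WT 2 and WT 3 relative to Tg 1 and Tg 3, which had no tract signal. Instead Tg 1 and Tg 3 lay -1.57 ± 0.26 (SE between arrays, 2 against 2) from WT 2 and WT 3, which argues against dilution as the cause of the lower level in Tg. The groups were already known to be apart in 8 of the 9 members. The sign of this difference was therefore given beforehand, and it is no independent test. WT 2 and WT 3 also lay 0.93 above WT 1, which is 1 mouse. Mast cells brought along by the tract were not tested and stay open, as does a genotype effect.

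Pomgnt2 and its direct neighbour among the measured genes, Gask1a (1.47 ± 0.32, chosen after its values were seen), were both higher in Tg and both highest in Tg 3. Among 27 genes at least 1 log2 unit higher at an unadjusted p under 0.01, this was the 1 pair within 3 genes of each other, and 1000 random gene orders gave 0.10 pairs on average (permutation p = 0.098). The other 19 genes within 10 places had a median of 0.12 and lay between -0.32 and 0.58. A local effect, such as the place of the transgene in the genome, may be a hypothesis for follow-up, but neither it nor cross-hybridisation of transgene RNA to unrelated probes is decided by 1 pair, and no probe or transgene sequence was used here.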
